A study of Mus musculus with 8 samples.

How the data were processed

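Cells of the dissected PVN were dissociated with papain, loaded on a 10x Genomics Chromium chip and made into 3' v2 single-cell libraries, per the labels. There were 8 libraries, 1 for each combination of sex, cohort and exposure, and no group had a replicate library. Reads were processed by the authors with Cell Ranger 3.0.2 and 3.1.0 against the mm10 mouse genome and cells were analysed with Seurat 3.1.3, per the submitters' processing notes; which library was run with which Cell Ranger version is not given in the sources used here. The deposited table has 1 line per cell with the experiment, the condition, the sex, the cell type (17 labels), the cluster (33 labels) and 6 numbers. Each cell was joined to its library through the names in these columns, with the experiment name for acute stress alone taken as the baseline cohort, and 0 cells were left unmapped. Gene expression was not used here.

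The numbers of UMIs and of genes per cell are whole-number counts in the deposited table. The mitochondrial share, deposited under a name that says percent, is a fraction: multiplied by the UMIs of the cell it gave a whole number within 1e-06 in every cell, and it was turned into percent here. The doublet, S and G2/M values are scores in the deposited table, and the tools that made them are not given in the sources used here. The deposited cells had 499 to 13323 UMIs, 351 to 3499 genes, a mitochondrial share of up to 30.0% and a doublet score of up to 4.00, and any filters behind these ranges are not given in the sources used here. No further doublet removal was done. A doublet score of 0 was given to 27.1% of cells.

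Cell types are the authors' deposited annotation and were not renamed. Before the data were examined, a rule placed labels in broad classes by words they contain (neurons, astrocytes, oligodendrocyte lineage, ependymal cells and tanycytes, immune cells, vascular and stromal cells); Meningeal cells matched none and stayed apart. Types named in the text were likewise fixed beforehand as the broad classes, the types past the threshold in a comparison, and the 3 types with the largest log2 fold in each direction for stressed against control and female against male. Interactions and clusters are outside that rule, and the types named there were chosen after their values were seen.

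Numbers of cells per type and library were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with all cells of a library as its size, no further normalization and no abundance trend. Libraries, not cells, were the replicates. The edgeR prior had 71.9 degrees of freedom for types and 6.11 for clusters in the comparisons of stress, sex and cohort. Intervals and p-values of types thus rest mostly on spread pooled over types. In the 2 interactions of types the prior was infinite, so their SEs and p-values rest wholly on that pooled spread. A type that varies more than others, such as one with unlike shares across libraries, gets no wider SE there. All 8 libraries entered each fit, with sex, cohort and exposure as terms, and with the sex by stress or cohort by stress term added for the interactions. Types or clusters with at least 80 cells over all libraries were tested, which kept 17 types and 32 clusters. P-values were adjusted by Benjamini and Hochberg over types within a comparison, with a threshold of 0.05. Broad classes were tested by exact two-sided sign-flip permutation of the 4 within-pair differences in log odds. Library medians of UMIs and genes per cell (log2), medians of mitochondrial percent and means of scores were tested with limma 3.58.1 in types with at least 10 cells in each library, 16 in all. In all, 6 measures were tested in 5 comparisons each, and numbers of cells in 5 comparisons at 2 levels, with no adjustment across these tests. The comparison of cohorts in depth, the alternatives for the scores, the sex by cohort term and the clusters with single libraries left out were added after the data were seen. Shares of single libraries carry exact Clopper-Pearson 95% intervals computed with scipy 1.17.1, which cover counting error only. Figures were drawn with matplotlib 3.10.9.

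The tests were first run on simulated data. With cell numbers drawn from the real shares and library sizes and from 1 spread common to all types (100 data sets of 17 types, changed types having under 5% of cells), the edgeR test recovered 63% of 2-fold and 100% of 4-fold changes for stressed against control, 58% and 99% for female against male, and 71% and 99% for the cohorts. For the sex by stress interaction it recovered 9% and 51%, and for restraint alone against chronic stress with restraint 8% and 59%. It called 0.467% to 1.47% of unchanged types, and 5% to 6% of data sets without any change had a call. Types were drawn independently of each other and clusters were not simulated. These rates need not hold where types differ in spread or move together within a library. In a first version of this simulation changed types could have any share, and more unchanged types were called, because a change in an abundant type shifts the share of all others; the limit on share was set after that was seen. The limma test recovered 78% to 91% of shifts of 4 residual SDs over the 6 measures (100 data sets of 16 types each).

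Alternatives were TMM factors, DESeq2 1.42.0 with its own size factors, limma on log2 odds with 0.5 cells added, no filter on cell number, cells with at least 1000 UMIs, cells with at most 10% mitochondrial UMIs, neurons left out, no covariates, the matched pair as a block, each library left out in turn, and each cohort alone. For depths they were means in place of medians, at least 30 cells per type and library, another moderation of the variance, and division by the library's median. For scores they were medians in place of means, the matched libraries as a block, and removal of the slope on log2 UMIs within a library. For classes they were the share itself in place of log odds, and for clusters the cells of the same class as library size.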

Results

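Single cells of the paraventricular nucleus of the hypothalamus (PVN), the brain region that starts the hormonal stress response, were profiled in C57BL/6 mice by droplet RNA sequencing. The 8 libraries cover both sexes in 2 cohorts, and each combination of sex, cohort and exposure is 1 library. In the baseline cohort (10 weeks of age), control mice stand against mice given 15 min of acute restraint stress (ARS). In the CMS cohort (11 weeks of age), controls stand against mice given the same restraint after 21 days of chronic mild stress (CMS). Tissue was taken 5 h after the restraint. The controls of the CMS cohort have titles that name CMS, but their condition is given as unstressed, and they are treated here as unstressed controls of that cohort.

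The table holds 35672 cells, each with its library, its cell type as annotated by the authors, its number of UMIs (unique molecular identifiers) and of detected genes, its mitochondrial share and 3 scores. Expression of single genes was not analysed here, so the comparisons below are of cell types and of properties of their cells. The female libraries held 4528 to 5777 cells and the male libraries 3523 to 3831. Total UMIs ran from 9924892 in the male baseline control library to 15760435 in the female baseline control library. The median cell of a library had 1845 (female CMS control) to 2565 (male baseline ARS) UMIs. Since each group is 1 library, intervals on single shares cover counting error only, and tests across libraries rest on what the matched pairs have in common. Nothing in the labels says how many animals a library holds, so p-values measure only the spread between these libraries.

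Astrocytes were the most numerous of the 17 annotated types, with 33.3% of all cells, followed by Oligodendrocytes (12.4%), Endothelial cells (9.01%), GABA neurons (7.44%), Microglia (7.05%) and Ependymal cells (6.90%). Neurons of all kinds made up 19.9% of cells. They comprised inhibitory GABA neurons, excitatory Glut neurons (4.0%), neurons labelled AVP after the vasopressin gene (2.64%) and a mixed group (5.84%). Vascular and stromal cells made up 15.1%, the oligodendrocyte lineage 14.9%, ependymal cells and tanycytes 8.72%, immune cells 7.69% and Meningeal cells 0.367%. COP, with 115 cells, was the rarest type. AVP neurons and COP had the highest median depths, 6141 and 6282 UMIs per cell, against 1283 in Astrocytes and 1200 in the mixed neurons.

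**Figure D1:**
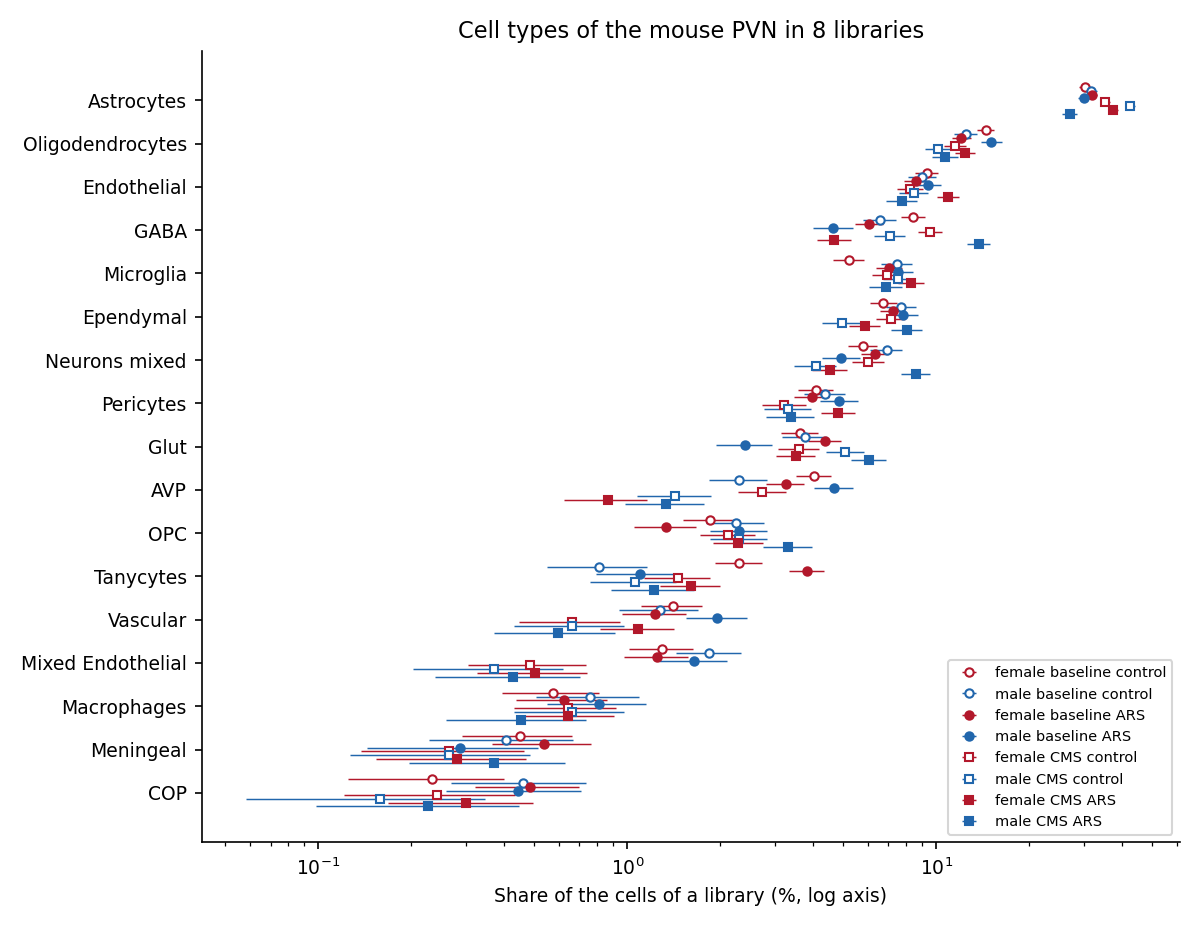
Share of each annotated cell type among the cells of a library (percent, log axis), with 95% Clopper-Pearson intervals as bars. Red marks female and blue male libraries, circles the baseline and squares the CMS cohort, open symbols controls and filled symbols stressed mice; the male CMS ARS library has the highest share of GABA neurons (13.7%) and the lowest of Astrocytes (27.0%).

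**Figure D2:**
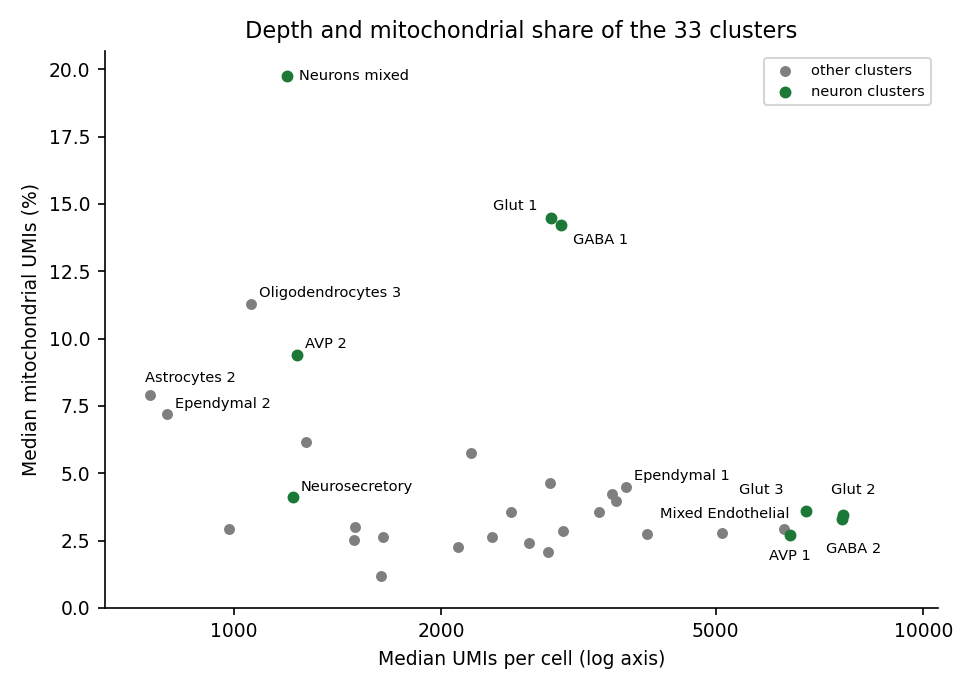
Median UMIs per cell (log axis) and median mitochondrial share (percent) of the 33 annotated clusters; green points are neuron clusters, grey points all others. Neuron clusters lie either at high depth and low mitochondrial share (GABA 2, Glut 2, Glut 3, AVP 1) or at lower depth, with a share from 4.11% (Neurosecretory) to 19.8% (mixed neurons).

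Stressed against control mice addressed whether acute restraint, alone or after chronic stress, was followed by a different mix of PVN cells. No cell type passed the test. Tanycytes, specialised ependymal cells of the ventricular wall, made up 1.93% ± 1.27 (SD, n = 4) of cells in stressed and 1.41% ± 0.653 in control libraries. Their share was higher in the stressed library of each of the 4 pairs, by ratios of 1.10 to 1.65, with a fitted log2 fold of 0.40 (SE 0.26). GABA neurons made up 7.28% ± 4.34 of cells in stressed and 7.89% ± 1.35 in control libraries, and the stressed share was lower in 3 of the 4 pairs. In female CMS mice it was 4.68% against 9.54% (ratio 0.490, 95% interval 0.420 to 0.572), whereas in male CMS mice it was 13.7% against 7.06% (ratio 1.94, interval 1.68 to 2.24).

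The edgeR quasi-likelihood test called 0 of 17 types, with 0 at an unadjusted p under 0.05 and a smallest adjusted p of 0.944; DESeq2 and limma also called 0. The other named types were COP (log2 fold 0.44, SE 0.34), Vascular cells (0.29, SE 0.27), AVP neurons (-0.23, SE 0.27) and Astrocytes (-0.14, SE 0.23). The 95% interval of the fold for Astrocytes ran from 0.666 to 1.24. Of the 17 types, 1 moved the same way in every pair, where chance gives 12.5% of types. At the finer level of the annotation, edgeR called 0 of 32 clusters with 0 at an unadjusted p under 0.05, and DESeq2 and limma called 0. Without the male CMS ARS library, the GABA share was 1.60-fold lower in stressed mice (log2 fold -0.68, SE 0.20, edgeR adjusted p = 0.0489; from 0.0489 to 0.991 over its alternatives), so that library decides whether a GABA decrease is called. Without the female CMS ARS library the GABA log2 fold was 0.0736 (edgeR adjusted p = 0.976), so the direction rests on that library as much.

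Among the broad classes, neurons differed most between pairs. Their share went from 21.9% in the female CMS control library to 13.6% (95% Clopper-Pearson interval 12.6 to 14.6) in the female CMS ARS library. In male CMS mice it went from 17.6% to 29.7% (28.2 to 31.2), while Astrocytes went from 42.5% to 27.0%. The baseline pairs differed less, with 21.8% against 20.0% in female and 19.5% against 16.7% in male mice. Over the 4 pairs, neurons made up 20.0% ± 6.97 of cells in stressed and 20.2% ± 2.05 in control libraries (exact two-sided sign-flip permutation test, n = 4 pairs, p = 0.75). Ependymal cells and tanycytes together made up 9.17% ± 1.47 and 8.04% ± 1.38 (exact p = 0.375), immune cells 8.06% ± 0.718 and 7.44% ± 1.15 (exact p = 0.375). The oligodendrocyte lineage made up 15.2% ± 1.80 and 14.6% ± 1.69, vascular and stromal cells 15.6% ± 2.60 and 14.5% ± 2.06 (exact p = 0.625 for each). Exact p was 0.875 for Astrocytes and 0.75 for Meningeal cells. With 4 pairs the test cannot go below 0.125, and 0 of 7 classes moved the same way in every pair.

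**Figure D3:**
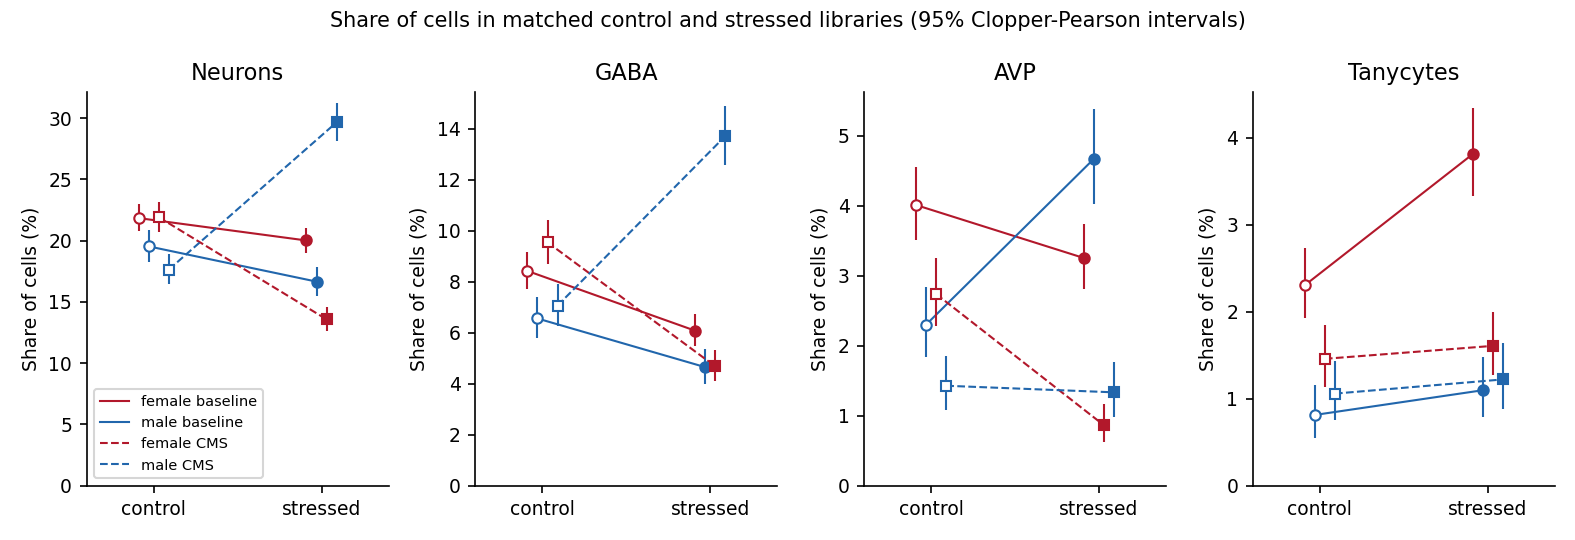
Share of cells (percent, bars: 95% Clopper-Pearson intervals) in control and stressed libraries for neurons of all kinds, GABA neurons, AVP neurons and Tanycytes; lines join matched libraries, red female and blue male, solid baseline and dashed CMS. Neurons and GABA neurons have opposite slopes in the female and male CMS pairs, and the Tanycyte share is highest in the female baseline ARS library (3.81%).

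Female libraries were set against male libraries matched on cohort and exposure. Tanycytes were the cell type that differed. They made up 2.29% ± 1.07 (SD, n = 4) of cells in female and 1.05% ± 0.171 in male libraries, a 2.08-fold higher share (95% interval 1.44 to 3.01; log2 fold 1.06, SE 0.27; edgeR adjusted p = 0.00322). The share was higher in the female library of each of the 4 pairs. The ratio was 2.83 and 3.47 in the baseline pairs and 1.38 and 1.32 in the CMS pairs. OPC, the oligodendrocyte precursors, had a lower share in the female library of each of the 4 pairs (log2 fold -0.43, SE 0.24), which did not pass the edgeR test (adjusted p = 0.728).

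Within cohorts, the Tanycyte share was 3.16-fold higher in female mice at baseline (95% interval 2.04 to 4.89) and 1.35-fold (0.866 to 2.09) in the CMS cohort. The Tanycyte call was made by limma on log odds and lost with DESeq2 (log2 fold 0.95, adjusted p = 0.102; adjusted p from 4.5e-05 to 0.234 over all alternatives of this result). Within edgeR it was lost with TMM factors (1.02, adjusted p = 0.141) and without covariates (1.13, adjusted p = 0.0913). It was also lost in edgeR without the female baseline ARS library (log2 fold 0.81, adjusted p = 0.234), the male baseline control library (0.88, 0.165) or the male baseline ARS library (0.87, 0.0937). The remaining named types, Meningeal cells (log2 fold 0.19), AVP neurons (0.16), Mixed_Endothelial cells (-0.16) and Glut neurons (-0.14), each had an edgeR adjusted p of 0.960. Of 17 types, 2 differed the same way in all 4 pairs, where chance gives 12.5%. None of the 7 broad classes did. The exact sign-flip p was 0.375 for ependymal cells and tanycytes (9.04% ± 1.49 in female, 8.17% ± 1.47 in male libraries), 0.75 for Astrocytes, 0.625 for immune and for Meningeal cells, and 1 for neurons (19.3% ± 3.94 and 20.9% ± 5.98), the oligodendrocyte lineage, and vascular and stromal cells.

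Among 32 clusters, edgeR called 0 between the sexes, with 3 at an unadjusted p under 0.05; DESeq2 and limma called 0. These 3, named here after their values were seen, were all higher in the female library of every pair. AVP_2, a cluster of AVP neurons with few UMIs, made up 0.469% ± 0.268 of cells in female and 0.180% ± 0.090 in male libraries (log2 fold 1.34, edgeR adjusted p = 0.0788). Oligodendrocytes_3 made up 1.33% ± 0.266 and 0.675% ± 0.275 (log2 fold 1.0, edgeR adjusted p = 0.0972), and the last was the Tanycyte cluster itself (log2 fold 1.05, edgeR adjusted p = 0.0788). Its cells are those of the Tanycyte type. Their unadjusted edgeR p was 1.9e-04 among types and 0.00492 among clusters, where the pooled spread weighs less. Median UMIs per cell were 1236 in AVP_2 and 1060 in Oligodendrocytes_3, against 3534 in Oligodendrocytes_1, but 3385 in the Tanycyte cluster. The median mitochondrial share was 11.3% in Oligodendrocytes_3 and 4.25% in Oligodendrocytes_1. For such shallow clusters sex cannot be told apart from cell number, since each female library held more cells than any male one. Of 33 clusters, 9 differed the same way in all 4 pairs, where chance gives 12.5%.

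Whether the response to stress differed by sex, the question in the title of the series, was tested as an interaction. AVP and GABA neurons had the largest differences; as the interaction has no rule for naming types, both were chosen after their values were seen. The AVP share was higher after restraint in male baseline mice, 4.67% against 2.30% (ratio 2.03, 95% interval 1.57 to 2.62). It was lower after restraint in female baseline mice, 3.25% against 4.01% (0.811, 0.670 to 0.982). After chronic stress with restraint it was lower in female CMS mice, 0.863% against 2.74% (0.315, 0.223 to 0.445). In male CMS mice the ratio was 0.934 (0.634 to 1.38). The female minus male log2 difference was -1.45 (SE 0.52, edgeR adjusted p = 0.122) for AVP and -1.06 (SE 0.49, edgeR adjusted p = 0.30) for GABA neurons.

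In this interaction edgeR called 0 of 17 types, with 2 at an unadjusted p under 0.05, and DESeq2 and limma called 0. With single libraries left out, the log2 difference ran from -1.99 to -0.943 for AVP. For GABA neurons it ran from -1.76 to -0.175, the latter without the male CMS ARS library. Without the male CMS ARS library the AVP interaction was called (-1.73, edgeR adjusted p = 0.00840), and without the male baseline ARS library the GABA interaction was called (-1.76, edgeR adjusted p = 0.00338); over all alternatives the adjusted p ran from 0.00840 to 0.954 for AVP and from 0.00338 to 0.961 for GABA.

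The effect of chronic stress with restraint was set against that of restraint alone, each measured against its own control. With the CMS controls taken as unstressed, the first effect is that of both exposures together, and the comparison cannot separate them. The AVP share again differed most, with a CMS minus baseline log2 difference of -1.26 (SE 0.55, edgeR adjusted p = 0.439), and GABA neurons had 0.60 (SE 0.52, edgeR adjusted p = 0.918). EdgeR called 0 of 17 types, with 1 at an unadjusted p under 0.05, and DESeq2 and limma called 0. With single libraries left out the AVP value ran from -1.80 to -0.643. The GABA value turned to -0.53 (edgeR adjusted p = 0.636; from 0.0501 to 0.994 over its alternatives) without the male CMS ARS library.

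The CMS cohort as a whole was set against the baseline cohort because the cohorts differ in age and in anything done to them apart. Only the stressed libraries of the CMS cohort are taken to have had chronic stress, so the cohort term is not a measure of it. In the CMS cohort 3 cell types had lower shares. Mixed_Endothelial cells made up 0.446% ± 0.0602 (SD, n = 4) of cells in the CMS cohort and 1.51% ± 0.285 at baseline, 3.29-fold lower (log2 fold -1.72, SE 0.28, edgeR adjusted p = 9.79e-07). Vascular cells made up 0.751% ± 0.224 and 1.47% ± 0.336, 1.93-fold lower (log2 fold -0.95, SE 0.27, edgeR adjusted p = 0.00443). AVP neurons made up 1.59% ± 0.804 and 3.56% ± 1.02, 2.31-fold lower (log2 fold -1.21, SE 0.27, edgeR adjusted p = 2.5e-04).

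EdgeR called 3 of 17 types (4 at an unadjusted p under 0.05), DESeq2 3 and limma 4, and among 32 clusters edgeR called Mixed_Endothelial alone (7 unadjusted). DESeq2 and limma on log odds each called more clusters than edgeR. Mixed_Endothelial was called under each alternative that was run (adjusted p from 1.14e-08 to 0.00127). The AVP call was lost with TMM factors (-1.03, edgeR adjusted p = 0.0642), with DESeq2 (-1.03, adjusted p = 0.0524), without the female CMS ARS library (-0.89, edgeR adjusted p = 0.119) and without the female baseline ARS library (-1.26, edgeR adjusted p = 0.0632), with adjusted p from 4.18e-05 to 0.119 over its alternatives. The Vascular call was lost with TMM factors (-0.78, edgeR adjusted p = 0.0642) and without the male baseline ARS library (-0.76, edgeR adjusted p = 0.0830), with adjusted p from 3.63e-04 to 0.0830. The Vascular cluster holds the same cells as the Vascular type and was not called (edgeR adjusted p = 0.0583). The clusters AVP_1 (edgeR adjusted p = 0.0877) and AVP_2 (0.0583) were not called either. The pooled spread weighs less among clusters.

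**Figure D4:**
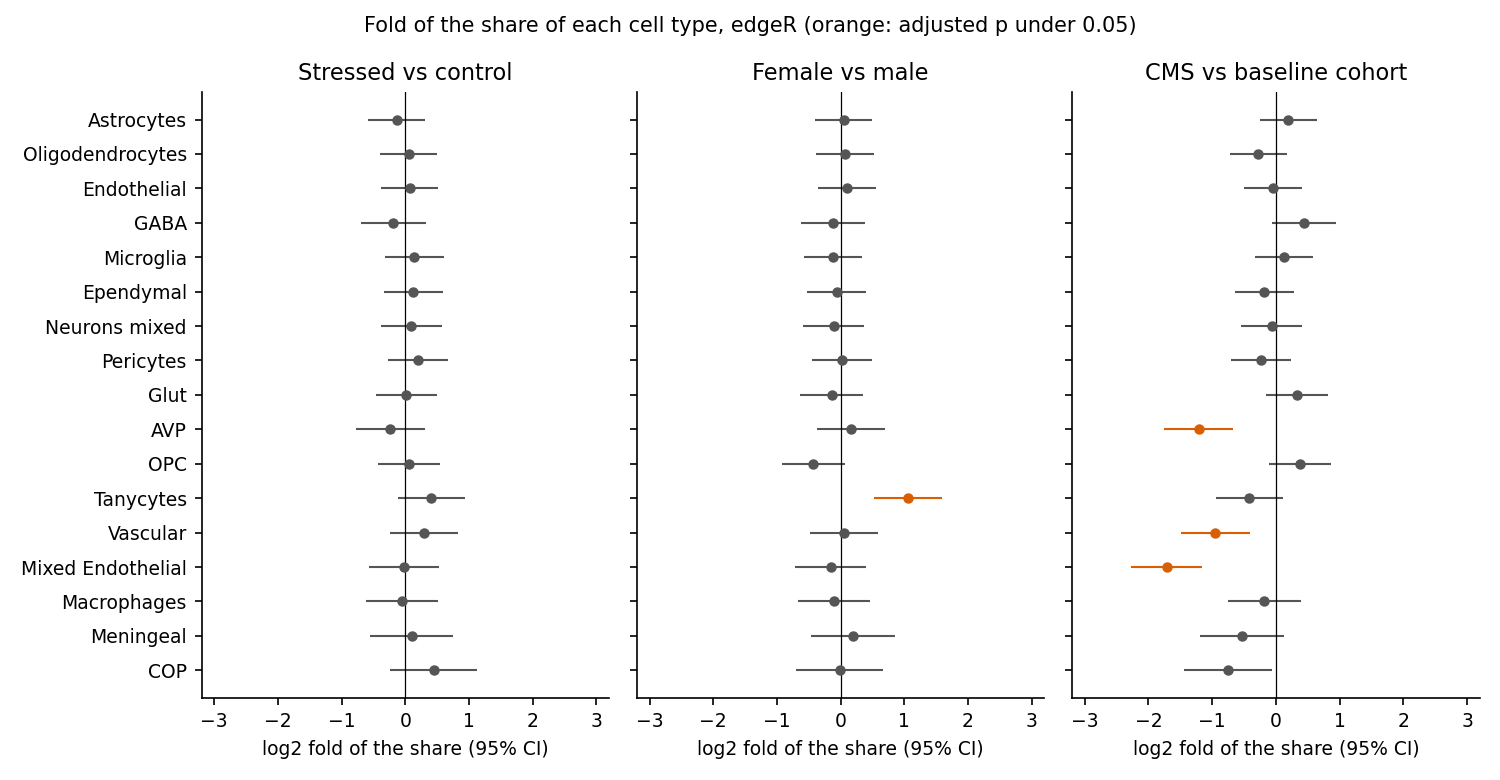
Log2 fold of the share of each cell type with its 95% interval from edgeR for stressed against control, female against male and CMS against baseline cohort (8 libraries; orange: adjusted p under 0.05). No type is orange for stress, Tanycytes (1.06) for sex, and AVP (-1.21), Vascular (-0.95) and Mixed_Endothelial (-1.72) cells for cohort.

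The depth of the cells was compared within each of 16 types, COP being left out for having too few cells. For stressed against control, limma called 0 of 16 types for UMIs per cell, genes per cell and mitochondrial percent, with 1, 0 and 1 at an unadjusted p under 0.05. Between the sexes, Meningeal cells, named after the coverings of the brain, had fewer genes per cell in female mice. Library medians, each of 10 to 31 cells, were 1161 ± 183 (SD, n = 4) against 1383 ± 122, 1.20-fold lower (log2 difference -0.26, SE 0.08, limma adjusted p = 0.0319) and lower in each of the 4 pairs. Their UMIs per cell, 1987 ± 402 against 2543 ± 281, missed the threshold (limma adjusted p = 0.0541). The genes-per-cell call was lost without any of 5 of the 8 libraries (limma adjusted p from 0.0706 to 0.372), which were the female baseline control, male baseline ARS, female CMS control, male CMS control and female CMS ARS libraries. It was also lost with the matched pair as a block (-0.26, adjusted p = 0.0823), with trend and robust moderation (-0.26, 0.166) and when values were divided by the library's median (-0.16, adjusted p = 0.305; from 7.52e-04 to 0.372 over all alternatives). For the sex by stress interaction limma called 0 of 16 types in each of the 3 measures, with 0 at an unadjusted p under 0.05.

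Between cohorts, the medians of GABA and Glut neurons were higher and that of Macrophages lower in the CMS cohort, while AVP and mixed neurons were not called. GABA neurons had a median of 4917 ± 570 (SD, n = 4) UMIs in the CMS cohort against 3877 ± 347 at baseline, 1.27-fold more, and Glut neurons 4787 ± 756 against 3528 ± 530, 1.35-fold more. Macrophages had 1884 ± 179 against 2376 ± 355, 1.25-fold fewer (limma adjusted p = 0.0436 for each of the 3). The UMI call was lost in 8 of 13 alternatives for GABA, 4 of 13 for Glut and 8 of 12 for Macrophages (limma adjusted p up to 0.280, 0.280 and 0.559). The mix of clusters within GABA neurons did not overlap between the cohorts. GABA_2, whose cells have a median of 7629 UMIs against 2979 in GABA_1, made up 32.6% to 35.5% of GABA cells in baseline and 37.8% to 50.6% in CMS libraries, though among all cells GABA_2 was not called (log2 fold 0.77, edgeR adjusted p = 0.209). In Glut neurons the cohorts overlapped, with Glut_2 and Glut_3 making up 23.7% to 39.7% of Glut cells in baseline and 28.8% to 55.4% in CMS libraries, and Glut_2 was not called either (log2 fold 0.81 among all cells, edgeR adjusted p = 0.174). The mitochondrial share, 8.35% ± 1.91 in the CMS cohort against 10.9% ± 1.69 at baseline in GABA and 7.90% ± 2.54 against 11.0% ± 2.19 in Glut neurons, was not called (limma adjusted p = 0.215 for both). The median of a type moves with the mix of its clusters, and depth within clusters was not tested. Genes per cell were 1.22-fold higher in GABA and 1.24-fold higher in Glut neurons, and 1.23-fold lower in Macrophages (limma adjusted p = 0.00349 for each) and 1.17-fold lower in Meningeal cells (limma adjusted p = 0.0247). Without the male CMS control library 1 of the 4 genes-per-cell calls was left, that of Meningeal cells, and the limma adjusted p of the other 3 was 0.0617. The GABA call was also lost without the female CMS ARS library (adjusted p = 0.138) and the Macrophage call without the male baseline ARS (0.137) or male CMS ARS library (0.0940). Over all alternatives the limma adjusted p ran from 6.35e-05 to 0.220 for GABA, from 4.78e-05 to 0.0617 for Glut and from 0.00175 to 0.377 for Macrophages. The Meningeal call was lost without any of 5 libraries (the female baseline ARS, male baseline ARS, female CMS control, female CMS ARS and male CMS ARS libraries; limma adjusted p from 0.0598 to 0.380) and with the block (0.0509), and over all alternatives its adjusted p ran from 2.54e-04 to 0.572. The mitochondrial share was lower by 0.69 percentage points in Macrophages (1.959% ± 0.161 against 2.65% ± 0.296; limma difference -0.69, adjusted p = 0.0213). It was 2.60% ± 0.0590 against 2.88% ± 0.0944 in Endothelial and 4.83% ± 0.214 against 4.36% ± 0.282 in Ependymal cells (limma adjusted p = 0.0435 for both). The 3 calls in UMIs per cell became 0 without the male CMS ARS or the male baseline ARS library and 1 without the female CMS ARS library, and the 3 mitochondrial calls became 0 without any of 5 libraries (all but the male baseline control and the 2 male stressed libraries).

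Scores per cell were compared as library means per type. The G2/M score, a score built from genes of late cell division, differed between the sexes in 4 of 16 types and by stress in 0. It was higher in female mice in Oligodendrocytes (-0.0144 ± 0.00119 against -0.0218 ± 4.0e-04, SD, n = 4; difference 0.0074, SE 0.0013, limma adjusted p = 0.0242), in Glut neurons (difference 0.0081, SE 0.0019, limma adjusted p = 0.0281) and in Mixed_Endothelial cells (difference 0.013, SE 0.0034, limma adjusted p = 0.0386). It was lower in OPC (difference -0.014, SE 0.0032, limma adjusted p = 0.0281). Each of the 4 differed the same way in all 4 pairs. With the matched pair as a block limma called 0 of the 16 types (adjusted p from 0.0508 to 0.0516 for these 4), and leaving out single libraries gave 0 to 7 calls. When medians replaced means, the OPC difference changed sign to 5.2e-04 and the Mixed_Endothelial call was lost (limma adjusted p = 0.275). Oligodendrocytes and Glut neurons stayed called (limma adjusted p = 0.0184 for both).

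For the other scores, limma called 0 of 16 types between stressed and control mice (1 at an unadjusted p under 0.05 for each of the S score, the doublet score and the G2/M score) and 0 between the sexes for the S score (0 unadjusted) and the doublet score (2 unadjusted). In the sex by stress interaction limma called 0 types for the S score (3 unadjusted) and the G2/M score (2 unadjusted) and 1, Meningeal cells, for the doublet score. Between cohorts it called 1 type for the S score, Tanycytes (0.0076 ± 0.0034 in the CMS cohort, 0.0170 ± 0.0028 at baseline; limma adjusted p = 0.0254; no alternatives were run for scores between cohorts), and 0 for the doublet score (3 unadjusted) and the G2/M score (1 unadjusted).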

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

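Alternatives for this result were chosen after it was seen. The doublet score of Meningeal cells was the result in which the effect of stress differed between the sexes. The female minus male difference of the stress effect was -0.481 (limma adjusted p = 0.0284; the adjusted p ran from 0.00174 to 1 over the alternatives). Mean scores were 0.716 in the male baseline ARS and 0.403 in the male CMS ARS library against 0.282 and 0 in their controls, and 0.299 and 0 in the female stressed libraries against 0.424 and 0. The type has 131 cells, 88.6% of them with a score of 0, and 0 types were called when medians replaced means or with the matched libraries as a block (adjusted p = 0.0713 for Meningeal cells). The call was lost without any of 6 of the 8 libraries, which were all but the male baseline control and male CMS control libraries (limma adjusted p from 0.0531 to 0.226). No explanation was tested.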

How the results depend on the processing

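Alternatives for scores, for cohort differences in depth and for clusters with single libraries left out were chosen after the data were seen; the others were fixed before. Of 402 alternative counts of calls, 319 stayed equal or within 1.5-fold. Of 528 alternative values of named types, 401 kept their direction and their side of the threshold or, without a test, lay within 1 SD. The values without a test were means over the 2 pairs of a cohort, and the SD came from the same 4 pairs. Such means nearly always lie within that SD, so their part of the 401 says little about stability. A count of 0 that stayed 0 was taken as equal. Where the main fit had a call, the count for composition stayed equal or within 1.5-fold in 16 of 17 alternatives by cohort and 11 of 17 by sex. Clusters by cohort did so in 9 of 18, UMIs and genes per cell by cohort each in 7 of 13, and mitochondrial percent by cohort in 4 of 12. Genes per cell by sex did so in 4 of 13, and the G2/M score by sex and the doublet score interaction each in 2 of 11. A fall from 3 calls to 2 is within this range, and like counts need not hold the same types. The 3 types that DESeq2 called by cohort did not include AVP neurons. The causes of the changes were not tested. Counts of called types were 1 for female against male, and became 0 with TMM factors, with DESeq2 and without covariates. For the cohorts they fell from 3 to 1 with TMM factors. Clusters differing by sex went from 0 to 3 when neurons were left out. Clusters differing by cohort went from 1 to 4 with DESeq2 or no filter on cell number, to 2 with limma on log odds, without neurons or with matched libraries as a block, and to 5 with the cells of the same class as library size (Mixed_Endothelial, Vascular, OPC, Oligodendrocytes_2 and GABA_2).

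For UMIs per cell, sex went from 0 to 1 with means and with the block, and cohort from 3 to 1 with the block and to 0 with trend and robust moderation. For genes per cell, the 1 sex call became 0 with the block, trend and robust moderation or division by the library median, and the 4 cohort calls became 2 with the division. With at least 30 cells per library these counts also became 0 and 2. That setting takes Meningeal cells and Macrophages out of the test, so it says nothing about their calls. The 3 cohort calls in mitochondrial percent became 0 with at least 30 cells, where Macrophages were not tested, and 5 with trend and robust moderation. The doublet score interaction went from 1 to 0 with medians and with the block, the S score interaction from 0 to 2 with the block, and the G2/M score by sex from 4 to 2 with medians and 0 with the block; the OPC difference with medians was 5.2e-04. The blocks match libraries by design, not by animal.

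With single libraries left out, counts of types ran from 0 to 1 for stress, for sex and for the sex by stress interaction, and from 2 to 3 for cohort. Counts of clusters ran from 0 to 2 for sex and from 1 to 3 for cohort. UMIs per cell gave 0 to 1 (sex) and 0 to 5 (cohort), genes per cell 0 to 1 and 1 to 4, and mitochondrial percent 0 to 3 (cohort). The doublet score gave 0 to 1 (stress) and 0 to 2 (interaction), the G2/M score 0 to 7 (sex, 7 without the male CMS ARS library) and 0 to 1 (interaction). With 1 of the 4 pairs left out, 1 to 2 of 7 classes moved the same way in the remaining 3 pairs for stress and 0 to 5 for sex, 5 without the CMS stressed pair. Log2 folds that changed sign ran from -0.60 to 0.13 (AVP), -0.68 to 0.07 (GABA) and -0.21 to 4.2e-04 (Astrocytes) for stress. AVP was above 0 without the female CMS control (0.07) or female CMS ARS library, GABA (0.0736) without the female CMS ARS library and Astrocytes without the male CMS ARS library. They ran from -0.0587 to 0.37 (Meningeal), -0.20 to 0.55 (AVP, -0.16 without the male baseline control and -0.20 without the female CMS control library) and -0.41 to 0.0650 (Glut) for sex, and from -0.53 to 1.42 for GABA in the comparison of chronic stress with restraint against restraint alone.

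No paired analysis by animal was possible because each group has 1 library and the labels give no animal numbers. The number of cells sets limits for rare types: COP, with as few as 6 cells in a male library, was left out of the tests of depth and scores.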

Other observations

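Neurons fell into clusters of very different depth and mitochondrial share. GABA_2 cells had a median of 7629 UMIs and 3.28% mitochondrial UMIs, against 2979 and 14.2% in GABA_1. Glut_2 (7649 UMIs, 3.47%) and Glut_3 (6747, 3.61%) stood against Glut_1 (2885, 14.5%) in the same way, and AVP_1 (6399, 2.70%) against AVP_2 (1236, 9.40%). Neurosecretory cells did not follow this, with few UMIs (1218) and a low mitochondrial share (4.11%). The cluster of mixed neurons had the highest median mitochondrial share of the 33, 19.8%. With the neurons of a library as its size, GABA_2 had a log2 fold of 0.68 between cohorts (edgeR adjusted p = 0.0354).

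Other cell types had marked properties of their own. Mixed_Endothelial cells, the type with the clearest cohort difference, had 5110 UMIs per cell and the highest median doublet score of the 17 types, 2.48, against 1.28 in Endothelial cells. Ependymal cells had the highest median G2/M score, 0.0520, and Tanycytes were next with 0.0162, while the other 15 types were below 0. The score alone is not read here as cell division.

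Tests of the patterns below were chosen after the result was seen, except those on shallow tanycytes and on other splits of the libraries. The tests on the depth of the G2/M score and on dividing cells as a whole use alternatives for scores, which were chosen after the data were seen. Their predictions refer to the called types, so the calls were known when these were written. The first pattern was the higher Tanycyte share in female libraries. More of the whole ventricular wall in the female samples is argued against by Ependymal cells, whose female to male log2 fold was -0.0648 with an upper 95% limit of 0.397, below the 1.06 of Tanycytes. Shallow cells taken for tanycytes are argued against by cells with at least 1000 UMIs, where the log2 fold was 1.10 (edgeR adjusted p = 0.00476). Preparations of the baseline cohort alone cannot be told apart from sex. The CMS minus baseline difference of the female to male log2 fold was -1.23 (95% interval -2.12 to -0.334, edgeR unadjusted p = 0.0105, adjusted p = 0.178). Before adjustment over types, the female excess was thus smaller in the CMS cohort, whose own interval includes no difference. Sex itself and a dissection reaching farther along the ventricle in female mice also stay open, and neither was tested.

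The second pattern was the G2/M score that differed between the sexes. Depth is argued against, since 4 of the 4 called types stayed called in limma when the slope of the score on log2 UMIs was removed. A few dividing cells are argued against in 3 of the 4 types (Oligodendrocytes, Glut and Mixed_Endothelial), where the difference of medians was 0.793 to 0.929 times that of means. In OPC, whose difference of medians was -0.0373 times that of means, a few high-scoring cells are a candidate explanation, with free RNA also open. The number of cells, and free RNA with it, cannot be told apart from sex, because the smallest female library held 697 cells more than the largest male one.

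The last pattern took the place of another that was dropped after its values were seen. The dropped pattern held 2 correlations across libraries, between the shares of deep cells in GABA and Glut neurons and between deep neurons and shallow non-neuronal cells. They are not reported as values because the libraries separate by cohort and the first correlation rested on 2 libraries.

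The pattern put in its place was the opposite departure of the 2 CMS stressed libraries, with neurons at 13.6% in the female and 29.7% in the male library. Exchanged sex labels were tested on the 8 of 16 types whose G2/M score separated the sexes in the other 6 libraries (chance gives 10% of types): by the midpoint between the means of the other female and male libraries, 4 put both with their labelled sex (GABA narrowly, its female value of -0.0206 being nearer to the other male libraries, -0.0265 to -0.0213, than to the other female ones, -0.0177 to -0.0155), 2 (AVP and Microglia) put both with the other sex and 2 were split. An exchange cannot be told apart from correct labels by this test, whatever its count, because the score itself is not separable from the number of cells. Shallow or damaged cells counted as neurons are argued against, because the male to female log2 ratio of the neuron share was 1.10 among cells with at least 1000 UMIs and at most 10% mitochondrial UMIs, against 1.13 among all cells. Recovery of neurons from the tissue of a single library and a response to chronic stress with restraint that differs by sex both stay open, since each rests on 1 library per group.

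Other splits of the 8 libraries into 4 and 4, 35 with the real one, were counted for each test. For composition by cohort 1 of 35 splits called as many types as the real one (3, highest other 1), for genes per cell by cohort 1 (4, highest other 2), for mitochondrial percent by cohort 1 (3, highest other 0) and for the G2/M score by sex 1 (4, highest other 1), so only the real split reached each of these counts. A share of 0.0286 is the smallest these splits can give and was not adjusted over the 21 counts, so chance is not excluded for these counts. The other design terms stayed in each fit, except that a term identical to the split was left out. For stress and sex, the split into cohorts was thus a test of the cohorts themselves, a factor of the design. Splits other than the real one can overlap in part with the remaining terms, which makes calls harder to reach in them. The G2/M count also fell to 0 with matched libraries as a block, and the mitochondrial count to 0 with at least 30 cells per type and library. With single libraries left out, the mitochondrial count fell to as low as 0 and the genes-per-cell count by cohort to as low as 1. Nor can chance be excluded for composition by sex (4 of 35 splits, real 1, highest other 3), genes per cell by sex (4, real 1, highest other 3), UMIs per cell by cohort (2, real 3, highest other 5) and clusters by cohort (3, real 1, highest other 1). For composition and genes per cell by sex the highest other split was the cohorts, so their highest other count belongs to a factor of the design. Within cohorts the Tanycyte share was 3.16-fold higher in female mice at baseline and 1.35-fold in the CMS cohort, and genes per cell by sex were not tested within cohorts.

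Where the real count was 0, all 35 splits gave as many. The highest other count was 3 for composition, 4 for clusters, 3 for UMIs, 4 for genes, 4 for mitochondrial percent, 1 for the doublet score, 1 for the S score and 4 for the G2/M score for stress. The split reaching it was the cohorts for composition, genes, mitochondrial percent and the S score, and the sexes for the G2/M score. For sex it was 6 for clusters, 3 for UMIs, 1 for mitochondrial percent, 1 for the doublet score and 1 for the S score, with the cohorts as that split for UMIs, mitochondrial percent and the S score. The split with 6 clusters was that of the sexes with the 2 CMS stressed libraries exchanged. It called Neurosecretory, AVP_2, GABA_2, Oligodendrocytes_3 and Tanycytes on 1 side and Astrocytes_3 on the other, against 0 for the labelled sexes, which points to a structure of the libraries that was not tested. For 3 of the 6 clusters the log2 fold was smaller with the 2 libraries exchanged than with the labelled sexes (AVP_2 1.15 against 1.34, Oligodendrocytes_3 0.92 against 1.0, Tanycytes 0.87 against 1.05), and for the other 3 it was larger (Neurosecretory 1.14 against 0.30, GABA_2 0.72 against -0.014, Astrocytes_3 -0.83 against -0.54).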
